A study of Mus musculus with 6 samples.

How the data were processed

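Microglia from naive mice and from mice at the peak of EAE were measured by MiGS (2 libraries per condition) and by RNA-seq (1 library per condition). Groups and replicate numbers come from the sample titles. Labels give 30 mice pooled per condition, with EAE induced at 24 to 28 weeks of age and cells separated on a 30% and 70% Percoll gradient before sorting; nothing says whether the MiGS replicates are separate pools of animals, so p-values measure the spread between these libraries, which can be partly technical. Per the submitters' processing notes, Bowtie2, TopHat, featureCounts and edgeR were used with build mm10; their roles and versions are not given in the sources used here.

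The RNA-seq table holds raw counts per Ensembl gene, per the file headers, beside FPKM values that the authors computed and that were not tested here. The counts came from a stranded library kit with ribosomal RNA depletion, per the labels' protocols; whether counting used the strand is not given in the sources used here, so overlapping genes and close paralogs are uncertain. Of 42303 rows, 506 had no symbol (0.0573% of naive counts) and stayed out of named genes and lists. Totals were 31282093 naive and 36561934 peak counts. The deposited MiGS files hold a signal value per 50 bp window. Low values showed it to be whole reads divided by a size factor per library: 100% of values came out whole within a tolerance of 0.001, and the factors equal median-of-ratios size factors of the windows with reads in all 4 libraries. A window absent from a library's file was taken as 0 reads. Isolated runs of windows had a median of 3 windows, so a fragment is counted in several neighbouring windows, neighbouring tests are not independent, and sums over windows count fragments several times. Chromosomes 1 to 19 were analysed; X and Y were not analysed here.

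RNA-seq counts were scaled by TMM (edgeR 4.0.16) and genes with at least 50 counts over both libraries were compared by the ratio of scaled counts, with 0.5 added to each count on the log2 scale. With 1 library per condition there was no test. The median log2 ratio of each list was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Genes with 0 naive counts are given against a floor of 3 counts. They lie above their list's median with this floor too, so the medians stay as given. Relative to TMM, the median log2 ratio of all genes moved by -0.09 with library totals, 0.07 with DESeq2 size factors and -0.14 with upper quartile scaling.

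The design chosen before the data were examined was a count test on MiGS reads in promoters, gene bodies and windows. Because the deposited values are scaled signal, the main test was limma 3.58.1 (moderated, with a variance trend) on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment at 0.05 over windows or genes with at least 20 recovered reads in total; fold changes are on that scale and understate low windows. The edgeR quasi-likelihood test with TMM, the count test of that design, was run on recovered reads as an alternative. Its use on recovered reads was settled after the data were seen. The edgeR run with a replicate block was added after seeing the data, and the edgeR run with DESeq2 size factors was planned. The gene table used (RefSeq, same build) was used without strand, so promoters were replaced by both gene ends, from 1000 bp outside to 500 bp inside the gene; gene bodies leave out 500 bp at both ends. Gene lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, for lists with at least 8 genes. Correlations across genes used 100000 permutations. Other tools were DESeq2 1.42.0, R 4.3.3, Python 3.11.15 and scipy 1.17.1.

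Lists were fixed before the data were examined, as was the rule for named genes: the 10 highest and 10 lowest ratios among genes with at least 200 counts, leaving out predicted, mitochondrial, ribosomal protein, immunoglobulin, T cell receptor, small nucleolar RNA, small nuclear RNA, microRNA and pseudogene names; the up to 4 list members with the largest absolute log2 ratio; the genes of the sort and reporters; and the windows and genes with the 3 smallest p in each direction where none passed, with windows within 1000 bp named once. Some genes that this rule names are not reported here. Steps were tested on simulated data with 200 changed features. In RNA-seq (14367 genes), 99.5% of 4-fold changes passed 2-fold and intervals covered 95.6% of true ratios. The simulated RNA-seq counts held counting error only, as the intervals assume, so this does not cover spread between animals or libraries. In MiGS with the spread of these libraries, 0% of 2-fold, 4-fold and 8-fold changes were recovered in windows and gene ends, and 2.99%, 28.4% and 90.9% in gene bodies. The MiGS simulations used a common spread for all features of a kind. They left out the unequal rise of signal between libraries and did not cover widespread changes. Alternatives covered scaling, filters, pseudocounts (0.5 and 4), loess offsets that remove a trend with abundance, merging to 1000 bp, wider ends (2000 bp), other tools, a replicate block and leaving out each library.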

Results

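Microglia were sorted on F4/80 and CD45 from the brains and spinal cords of mice that carried a red reporter in 1 copy of Ccr2 and a green reporter in 1 copy of Cx3cr1. Naive mice were compared with mice at the peak of experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis induced by immunisation with a peptide of myelin oligodendrocyte glycoprotein (residues 35 to 55). Cells of 30 mice were pooled per condition. DNA methylation was measured by MiGS, in which a methyl-CpG binding domain captures methylated DNA fragments for sequencing, in 2 libraries per condition. RNA was sequenced in 1 library per condition, with 31282093 counts in the naive and 36561934 counts in the peak library. The RNA-seq differences have no replicate check, so they describe 2 libraries, and no p-value is given for them. Intervals of RNA-seq ratios are exact (Clopper-Pearson) 95% intervals and cover counting error only.

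The first comparison asked how the transcriptome of the sorted cells differed between the peak of disease and the naive state. Of 14367 genes with at least 50 counts, 1666 were at least 2-fold higher and 1344 at least 2-fold lower in the peak library. Which side held more genes turned with scaling: library totals gave 1495 higher and 1550 lower genes, and upper quartile scaling 1432 and 1686. Large differences lay almost all on one side: 427 genes were at least 8-fold higher and 3 at least 8-fold lower. Those 3, named after their values were seen, were Gm37108 (62 naive and 1 peak counts, 68.1-fold lower, interval from 11.8 upward), Oca2 (46 and 5 counts, 10.1-fold lower, interval 4.03 to 32.6) and Myo5c (56 and 7 counts, 8.79-fold lower, 3.998 to 22.9). Acod1, the enzyme that makes itaconate in activated macrophages, had 4 naive and 6788 peak counts (1544-fold, interval 603 to 5669). Il12rb1, a subunit of the interleukin 12 receptor, had 1 naive and 1918 peak counts (1745-fold, interval from 313-fold upward). Arg1 (arginase) was 711-fold higher, the acute phase gene Saa3 589-fold and the lysosomal glycoprotein gene Gpnmb 268-fold. AA467197, Cfb and Btnl6 had 0 counts in the naive library. Against a floor of 3 counts they were 154-fold, 152-fold and 92.8-fold higher. These are not lower limits, since the interval of each gene begins below its value. Ifi205 and F10 had 1 naive count each and 429 and 388 peak counts. Among genes with at least 200 counts, with the name exceptions of the rule, the lowest ratios included those of Rn7s1 (5.36-fold lower), CT010467.1 (5.15-fold), Sostdc1 (4.75-fold), Unc79 (4.72-fold), Hba-a2 (4.65-fold), Mycl (4.51-fold), Tgfbr3 (4.48-fold), Fras1 (4.47-fold), F5 (4.46-fold) and Frem1 (4.44-fold). Counting only genes whose whole interval lay beyond 2-fold left 1269 higher and 616 lower genes.

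Genes of resting microglia were lower and genes of disease-associated microglia higher in the peak library. Monocyte markers were higher in the same library (median log2 ratio 2.97), so the values of this and the following lists belong to the sorted cells as a whole. Of 26 measured homeostatic genes, 6 were at least 2-fold lower, 20 were neither and 0 were higher, with a median log2 ratio of -0.74 (percentile 0 among 10000 random lists matched on expression). Upk1b was 3.22-fold lower, the fructose transporter gene Slc2a5 2.49-fold, Fcrls 2.34-fold and Selplg 2.18-fold. Of 26 disease-associated genes, 18 were higher and 0 lower (median 1.84, percentile 100). Ch25h, which makes 25-hydroxycholesterol, was 54.1-fold higher, the cystatin gene Cst7 52.0-fold and the galectin gene Lgals3 35.7-fold. The genes behind the sort and the reporters differed less. Cx3cr1 went from 126234 to 73129 counts (1.90-fold lower, interval 1.88 to 1.91), Ccr2 from 542 to 1059 (1.78-fold higher, 1.60 to 1.98) and Ptprc, which encodes CD45, was 1.62-fold higher. Adgre1, which encodes F4/80, was 1.07-fold higher, and its log2 ratio turned to -0.03 with upper quartile scaling.

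**Figure D1:**
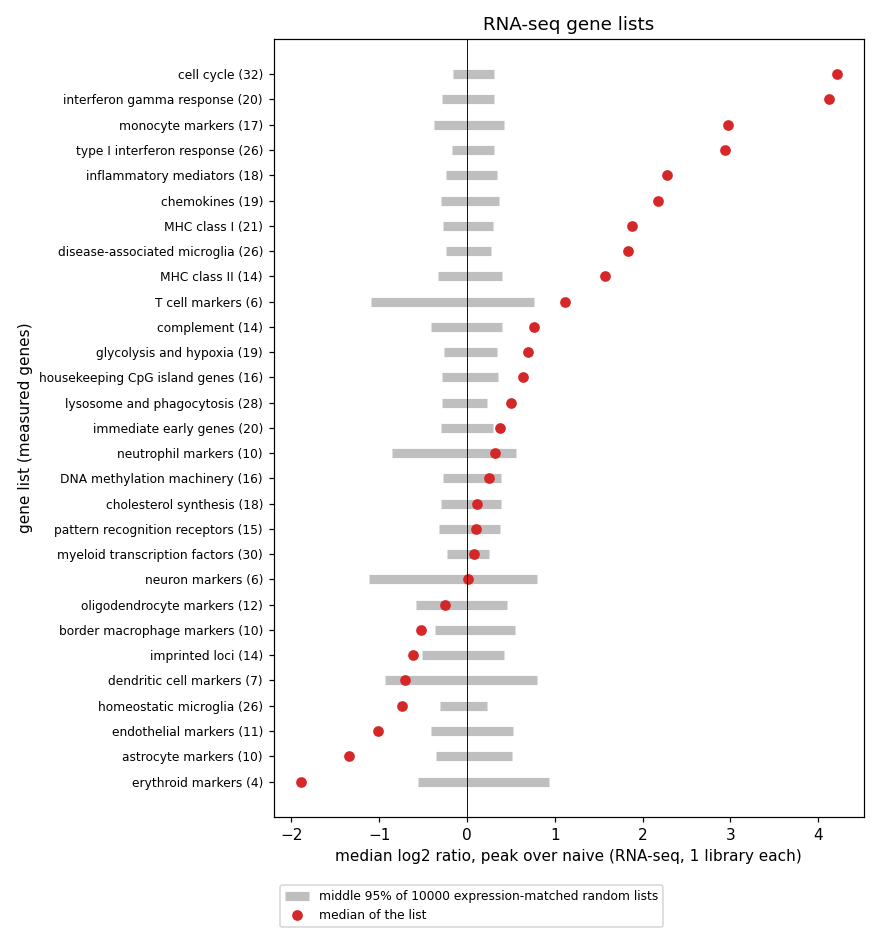
Median log2 ratio of peak over naive RNA-seq counts for each gene list fixed in advance with at least 4 measured genes (red points, number of measured genes in brackets), with the middle 95% of medians of 10000 random lists matched on expression (grey bars). Cell cycle (4.21) and interferon gamma response (4.13) have the highest medians, and erythroid (-1.90) and astrocyte markers (-1.35) the lowest.

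Antigen presentation and interferon response genes were mostly higher at peak. Of 14 MHC class II and co-stimulation genes 10 were higher and 0 lower (median 1.57, percentile 100), among them the co-stimulatory receptor Cd40 (29.1-fold), the class II transactivator Ciita (15.9-fold), the invariant chain Cd74 (10.2-fold) and H2-Ab1 (9.02-fold). Of 21 MHC class I genes 18 were higher (median 1.88, percentile 100), with H2-Q7 at 77.7-fold, H2-Q6 at 41.3-fold, the class I transactivator Nlrc5 at 17.8-fold and H2-Q4 at 10.8-fold. The H2-Q genes are close paralogs, so reads may be split between them. Of 26 type I interferon response genes 24 were higher (median 2.94, percentile 100), led by the nucleic acid sensor Zbp1 (53.9-fold), Oasl1 (23.4-fold), Oas3 (21.9-fold) and Ifit2 (19.3-fold). Of 20 interferon gamma response genes 19 were higher (median 4.13, percentile 100). Gbp6 was 150-fold, the chemokine gene Cxcl9 143-fold and the GTPase gene Iigp1 109-fold higher. Gbp11 had 0 naive and 86 peak counts (26.1-fold against the floor of 3 counts, interval from 20.8-fold upward).

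Chemokine, cytokine and complement genes followed with wider spreads within each list. Of 19 chemokine genes 13 were higher and 3 lower (median 2.17, percentile 100). Cxcl13, which attracts B cells, was 227-fold and Ccl5 114-fold higher. Cxcl11 had 0 naive and 129 peak counts (39.1-fold against the floor of 3 counts, interval from 31.4-fold upward). Of 18 inflammatory mediators 13 were higher and 1 lower (median 2.28, percentile 100), among them the inducible nitric oxide synthase gene Nos2 (75.8-fold) and Il12b with 1 naive and 164 peak counts. Of 14 complement genes 6 were higher and 8 neither (median 0.76, percentile 99.9). The central component C3 was 102-fold, C4b 39.0-fold and the inhibitor Serping1 24.7-fold higher. Of 15 pattern recognition receptors 5 were higher and 1 lower (median 0.10). Tlr11 was 5.14-fold, Tlr2 3.49-fold and Nod2 3.46-fold higher, and Tlr5 was 3.49-fold lower.

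Of 32 genes of DNA replication and mitosis 30 were higher and 0 lower (median 4.21, percentile 100). The spindle checkpoint kinase gene Bub1 was 51.2-fold, Ube2c 46.7-fold, Aurkb 45.0-fold and the mitotic cyclin gene Ccnb1 39.7-fold higher. Among 16 genes of the DNA methylation machinery 4 were higher, 1 lower and 11 neither (median 0.25, percentile 88.0). Uhrf1, which brings the maintenance methyltransferase to newly replicated DNA, had 79 naive and 1993 peak counts, and Gadd45b, Apobec1 and Mbd2 were 2.42-fold, 2.35-fold and 2.35-fold higher. Of 28 lysosome and phagocytosis genes 11 were higher and 1 lower (median 0.51), with the scavenger receptors Cd36 and Msr1 at 29.6-fold and 9.22-fold, the receptor kinase Axl at 8.61-fold, and Atp6v0d2 at 1 naive and 58 peak counts. Of 19 glycolysis and hypoxia genes 8 were higher (median 0.70), among them Pkm (3.88-fold), Hk3 (2.99-fold), Ldha (2.99-fold) and Tpi1 (2.91-fold). Of 18 cholesterol synthesis genes 1, Idi1, was higher (2.25-fold, median of the list 0.12), with Hsd17b7 at 1.65-fold higher. Of 30 myeloid transcription factors 5 were higher and 25 neither (median 0.07), with Bhlhe40 at 6.09-fold, Relb at 2.60-fold and Cebpb at 2.30-fold. Of 20 immediate early genes 3 were higher (median 0.38), namely Socs3 (6.74-fold), Ier3 (3.25-fold) and Egr3 (3.16-fold), and Egr1 was 1.98-fold higher.

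Markers of other cells moved in both directions. Of 17 monocyte markers 14 were higher and 0 lower (median 2.97, percentile 100). F10 had 1 naive count, Ly6c2 was 61.5-fold and the haptoglobin gene Hp 16.2-fold higher, and the fibronectin gene Fn1 had 816 naive and 35840 peak counts. Of 6 T cell markers with enough counts 4 were higher (median 1.11, and 2.65 with a minimum of 10 counts), with Il2rb going from 4 to 63 counts, Cd5 at 2.60-fold, Cd4 at 2.27-fold and Thy1 at 2.10-fold. Of 10 neutrophil markers 2 were higher (Cxcr2 7.93-fold, Mmp8 4.04-fold) and 2 lower (Camp 3.71-fold, Ngp 2.41-fold), with a median of 0.32. Of 10 border macrophage markers Clec4n (6.21-fold) and Siglec1 (3.52-fold) were higher, and Lyve1 (4.36-fold) and Pf4 (2.23-fold) lower, with a median of -0.52. Of 7 dendritic cell markers 3 were lower, Fscn1 (2.76-fold), Cd209a (2.73-fold) and Klrd1 (2.40-fold), and Flt3 was 1.64-fold lower (median of the list -0.71). Klrd1 was also the only NK cell marker with 50 counts, and of 2 B cell markers Ebf1 was 5.17-fold and Cd79b 1.38-fold lower. Of 10 astrocyte markers 7 were lower and 1 higher (median -1.35, percentile 0), with Slc4a4, Agt, Aqp4 and Gja1 between 2.63-fold and 2.77-fold lower. Of 11 endothelial markers 7 were lower (median -1.01, percentile 0), among them Tek (2.87-fold), Slco1a4 (2.75-fold), Emcn (2.64-fold) and Pecam1 (2.29-fold). The 4 measured erythroid markers were lower (median -1.90), with Hbb-bt at 3.76-fold, Hba-a1 at 3.69-fold, and Hbb-bs with 2410 naive and 882 peak counts. Of 12 oligodendrocyte markers 2, Olig1 (2.68-fold) and Olig2 (2.26-fold), were lower, Pdgfra and Mog were 1.82-fold and 1.72-fold lower, and the median was -0.25, which turned to 0.26 with a minimum of 200 counts. None of 6 neuron markers reached 2-fold (median 0.01): Camk2a and Eno2 were 1.94-fold and 1.58-fold lower, and Nefl and Tubb3 1.82-fold and 1.44-fold higher. Of 16 housekeeping genes 5 were higher (median 0.64, percentile 99.9), including B2m (3.67-fold), Gusb (2.22-fold), Eef1a1 (2.13-fold) and Rpl13a (2.06-fold). This median was close to those of glycolysis and hypoxia (0.70) and complement genes (0.76), so shifts of that size were not particular to those lists. Of 14 genes at imprinted loci 5 were lower (median -0.61), among them Mest (3.93-fold), Peg10 (3.25-fold), Grb10 (3.24-fold) and Nnat (2.67-fold). The 2 measured germline genes were Brdt (1.57-fold higher) and Tex14 (1.47-fold lower).

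The second comparison asked where captured, methylated DNA differed between the same conditions. The MiGS values covered 2915907 windows of 50 bp on chromosomes 1 to 19 (build mm10), and 1291322 windows held reads in all 4 libraries. Reads summed over windows came to 30424742 and 36501153 in naive replicates 1 and 2 and to 43970332 and 35285601 in peak replicates 1 and 2. A group of 474 windows with over 2000 reads each, most of their reads in a cluster on chromosome 2 (98662151 to 98667450), held 55.0%, 43.5%, 56.2% and 44.7% of these reads. Gene ends of germline genes, which are methylated in somatic cells, carried far more signal than those of housekeeping genes in every library. Per kb, 17 germline genes had a mean of 123 and 432 in the naive and 68.3 and 176 in the peak libraries (278 ± 218 and 122 ± 75.9, SD, n = 2), 13 imprinted loci 78.7 and 278 against 49.6 and 95.1 (179 ± 141 and 72.3 ± 32.1), and 16 housekeeping genes 0.756 and 2.39 against 2.15 and 1.19 (1.58 ± 1.16 and 1.67 ± 0.682). Outside the windows with over 2000 reads, the share of reads per chromosome differed little between libraries, from 5.36% to 6.17% on chromosome 7, the widest range.

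**Figure D2:**
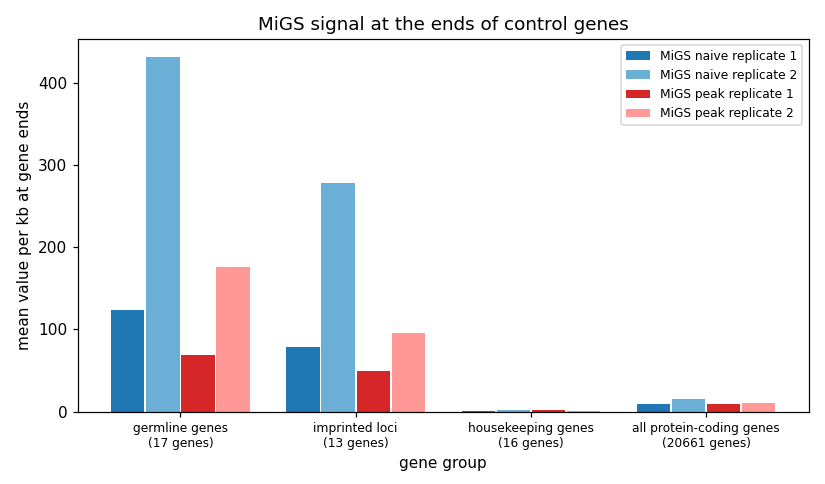
Mean MiGS value per kb at gene ends (reads divided by the library's size factor) for each of the 4 libraries, over 17 germline genes, 13 imprinted loci, 16 housekeeping genes and 20661 protein-coding genes. Germline genes reach 432 in naive replicate 2 and 68.3 in peak replicate 1, and housekeeping genes stay at or below 2.39 in each library.

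The libraries differed in how steeply signal rose from weakly to strongly captured windows. With the tested windows in 10 equal groups ordered by mean signal, the mean log2 value from the lowest to the highest group ran from 1.09 to 6.46 in naive replicate 2 and from 3.10 to 4.23 in peak replicate 1, with naive replicate 1 (2.24 to 5.25) and peak replicate 2 (2.47 to 5.42) between them. Both naive libraries rose more than both peak libraries, naive replicate 1 only narrowly more than peak replicate 2. Across windows, which are not independent replicates, Pearson's r was 0.653 between the naive and 0.439 between the peak libraries, and from 0.269 to 0.714 between libraries of different conditions.

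**Figure D3:**
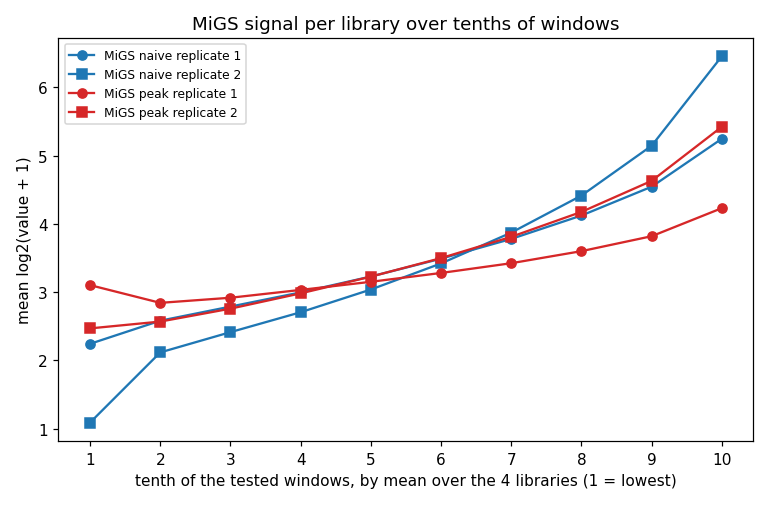
Mean log2(value + 1) per MiGS library (vertical axis) over 10 equal groups of the 936715 tested windows ordered by their mean over the 4 libraries (horizontal axis). Naive replicate 2 has the steepest line (1.09 to 6.46) and peak replicate 1 the flattest (3.10 to 4.23).

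No window passed an adjusted p of 0.05 between 2 naive and 2 peak libraries: limma called 0 of 936715 windows higher and 0 lower, with 42797 windows at an unadjusted p under 0.05, where chance alone gives 46836. On the recovered reads, edgeR without a replicate block and DESeq2 called 0 windows as well. With a block on the replicate numbers, whose meaning the labels do not give, edgeR called 3063 windows higher and 46157 lower. With the spread of these libraries, simulated windows changed 8-fold were recovered in 0% of cases, so changes of that size were not detectable. The 3 windows with the smallest p for higher signal at peak, none of which passed (limma, adjusted p = 0.818), lay in Dhx8 (chromosome 11, 101740301 to 101740350; log2 change 3.41, SE 0.69; 4 and 0 naive against 33 and 26 peak reads), in Ascc2 (chromosome 11, 4646601 to 4646650; 3.39, SE 0.69; 5 and 0 against 27 and 37 reads) and 15862 bp from Rfx8 (chromosome 1, 39736851 to 39736900; 2.86, SE 0.61; 4 and 1 against 33 and 26 reads). Those for lower signal lay between genes: on chromosome 12 (20791451 to 20791500; 14 and 36 naive against 0 and 7 peak reads), chromosome 6 (9868151 to 9868200; 22 and 43 against 2 and 8) and chromosome 1 (48362201 to 48362250; 10 and 44 against 1 and 5), with log2 changes of -3.38, -3.02 and -3.06 and the same adjusted p. Leaving out 1 library decided the count: without naive replicate 1, 24701 windows were called higher and 9498 lower, and without naive replicate 2, 33 were called higher.

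Gene ends and gene bodies gave the same count of calls. Limma called 0 of 10603 gene ends (562 at an unadjusted p under 0.05, 530 by chance, lowest adjusted p = 0.257) and 0 of 16591 gene bodies (494, 830 by chance, lowest adjusted p = 0.957). On the recovered reads, edgeR without a replicate block and DESeq2 called 0 of each. With the block, edgeR called 17 gene ends higher and 279 lower, and 59 and 585 gene bodies. Simulated 8-fold changes were recovered in 0% of gene ends and 90.9% of gene bodies, and 2-fold changes in 2.99% of gene bodies. The gene ends with the smallest p, none of which passed, included those of Cela1, Fibp and Arhgap9 with higher and Lipe and Tysnd1 with lower signal at peak. At Arhgap9 (chromosome 10, 127321913 to 127329947) the values per kb were 10.6 and 6.58 in the naive and 33.4 and 39.2 in the peak libraries (log2 change 2.07, SE 0.57, adjusted p = 0.470), while RNA-seq counts of this gene were 1.21-fold higher at peak. At Cela1 and Fibp naive replicate 2 alone stood apart, with 0 and 1.16 per kb against 33.3 and 31.4 in naive replicate 1. Among gene bodies the smallest p belonged to Kcnj10, Acot3 and Ogfrl1 with higher and Krt14, Sult2a8 and Sirpb1a with lower signal. Kcnj10, an inward rectifier potassium channel gene (chromosome 1, 172341210 to 172374085), had 3.95 and 3.72 per kb in the naive and 15.2 and 9.02 in the peak libraries (log2 change 1.60, SE 0.45), and Krt14 141 and 295 against 51.4 and 101 (-1.50, SE 0.45), both with an adjusted p of 0.957.

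Of 18 gene lists with at least 8 tested gene ends, 1 passed. Gene ends of 17 germline genes were lower at peak (median log2 change -1.02) in camera with a preset correlation of 0.01 (adjusted p = 1.33e-04). The call was lost with an estimated correlation (adjusted p = 0.979) and with loess offsets. It was kept with ends widened to 2000 bp (camera adjusted p = 7.93e-04) and with a replicate block. The highest of the 10 equal groups of windows by mean signal had a similar mean log2 change of -1.02. Fry, which sets a list against no change and not against the other genes, gave an adjusted p of 0.868. The peak libraries did not both lie below the naive ones: peak replicate 2 (176 per kb) was above naive replicate 1 (123). Gene ends at 12 imprinted loci had a median change of -1.003 and a mean of -0.61 (camera adjusted p = 0.0595). Among lists that were higher in RNA-seq, gene ends of 16 type I interferon response genes had a median change of 0.23 (camera adjusted p = 0.977), those of 9 inflammatory mediators 0.17 (0.534), those of 10 MHC class I genes 0.40 (0.838), with 1 gene adjusted over the list alone and 0 over all genes (H2-T22, named after its values were seen: 4.54 and 3.87 per kb naive against 25.4 and 15.8 peak), and those of 19 cell cycle genes 0.32 (0.963). The other 12 lists had adjusted p-values of 0.200 or more. The interferon gamma response, monocyte and chemokine lists had fewer than 8 tested gene ends and were not tested. Camera's direction was down while median and mean were above 0 for the type I interferon response, homeostatic, complement and cholesterol synthesis lists. It was also down where median and mean differed in sign, for inflammatory mediators (0.17 and -0.19), disease-associated genes (-0.23 and 0.12) and glycolysis and hypoxia (-0.09 and 0.05).

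The third comparison set the MiGS change of each gene beside its RNA-seq ratio. Across 6486 genes, which are not independent replicates, the change at gene ends showed no detectable relation to the RNA-seq ratio (Spearman's rho -0.01, permutation p = 0.626, adjusted p = 0.784 over 4 correlations; Pearson's r 0.0034). Across 11027 gene bodies rho was 0.07 (permutation p = 1e-05, the smallest these permutations can give, adjusted p = 2e-05). These permutations shuffle genes, so their p-values leave out the spread between libraries. The gene-body rho was not refitted with loess offsets or without 1 library, so it only describes these libraries. The median change at gene ends was 0.13 for 701 genes at least 2-fold higher in RNA-seq, 0.10 for 725 lower genes and 0.31 for 5060 others. In gene bodies these medians were -0.08, -0.18 and -0.09 for 1133, 1132 and 8762 genes.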

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

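EdgeR with a replicate block, the pseudocounts, and library totals or tests without windows of over 2000 reads were chosen after seeing the data. EdgeR with TMM and fry were in the design made beforehand. Their use on recovered reads and on gene ends, respectively, was settled after the data were seen. The MiGS counts of 0 stayed at 0 under library totals, loess offsets, DESeq2, edgeR without a block, both pseudocounts, an adjusted p under 0.1 and merging to 1000 bp, except as follows. A minimum of 40 reads called 24 windows lower, 6 of them with over 2000 reads; ends widened to 2000 bp called 2 genes lower; library totals without windows of over 2000 reads called 1 gene body lower. The cause was not tested. Leaving out each library in turn gave 0 to 24701 windows higher and 0 to 9498 lower, where the lone library of a condition is assumed to vary like the other group, and 0 gene ends and gene bodies. Restriction to autosomes was not run as an alternative, since only chromosomes 1 to 19 were analysed. Under other scalings RNA-seq gave 1495 higher and 1550 lower genes (library totals), 1432 and 1686 (upper quartile) and 1808 and 1213 (DESeq2 size factors), against 1666 and 1344 with TMM. With TMM, RNA-seq counts moved with the filter: 2227 higher and 2137 lower genes at 10 counts, 1282 and 696 at 200, 4212 and 3835 with no filter, and 1269 and 616 when the whole interval had to lie beyond 2-fold, where more or fewer genes qualify by construction. These filters were not combined with other scalings. Of 24 named genes, Adgre1 turned to a log2 ratio of -0.0326 with upper quartile scaling. Of 115 settings over 29 list medians, 6 moved by more than the spread of the random lists: at 10 counts T cell markers (2.65), chemokines (2.65) and inflammatory mediators (1.97), and at 200 counts inflammatory mediators (2.08), interferon gamma response (3.66) and oligodendrocyte markers (0.26, from -0.25). The rank correlation at gene ends (-0.0061) was -0.0357 at 200 counts, 0.019 with wide ends, 0.0656 in gene bodies and 0.0034 as Pearson's r, and from -0.0135 to 0.0072 without 1 library. The germline list was the 1 list called, also with ends widened to 2000 bp. With an estimated correlation or with loess offsets 0 lists were called. Fry, which sets a list against no change, called 0 lists.

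The MiGS replicate numbers 1 and 2 occur in both conditions, and the labels do not say that a number marks a shared animal, batch or day. The difference between replicates 1 and 2 in the naive condition correlated with that in the peak condition (0.398 over windows, 0.196 with loess offsets, 0.150 at gene ends). With 2 libraries per condition, swapping the numbers in 1 condition only turns the sign of these correlations. They therefore cannot show that the numbers mark pairs. With a replicate block, limma called 2469 windows higher and 67651 lower, 57 and 431 gene ends, 4 and 146 gene bodies, and 2 lists. With replicate block and loess offsets the counts were 1002 and 1383, 9 and 22, and 128 and 417. In edgeR with the block they were 3063 and 46157, 17 and 279, and 59 and 585. These fits keep 1 residual degree of freedom, and no paired effect is read from them.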

Other observations

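The gene families of the next paragraph and the tests on other cell types, scaling and monocytes were chosen after the results were seen; the 2 tests of library likeness were written down before their values were computed.

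Markers of the choroid plexus (Sostdc1, among the 10 lowest genes, is one of them), the epithelium that makes cerebrospinal fluid, were lower in the peak RNA-seq library as a group: 14 of 14 measured genes were at least 2-fold lower, with log2 ratios between -2.24 and -1.60 (median -1.95). This list was put together after the values of its genes could be seen, so a comparison with random lists would be void and is not given. Collagen genes had a median of -0.91 over 19 genes, 9 of them at least 2-fold lower. On the other side, 42 of 56 replication-dependent histone genes were at least 2-fold higher (median 2.14), and 31 of 82 ribosomal protein genes (median 0.83), with smaller shifts in proteasome subunits (median 0.50, 8 of 47 at least 2-fold higher), translation initiation factors (0.38, 5 of 54) and NADH dehydrogenase subunits (0.43, 0 of 34). Tripartite motif genes stood at 0.11 over 40 genes and claudins at -1.01 over 5. MiGS signal per kb in gene bodies was related to RNA-seq level in each library (Spearman's rho 0.208, 0.204, 0.222 and 0.216), but not in steps: with genes in 3 equal groups by expression, the median was 4.83, 11.7 and 11.3 from the lowest to the highest group in naive replicate 2, and the highest group lay below the middle one in the other libraries too. At gene ends rho was between 0.01 and 0.06. The CpG density of these regions was not analysed, so these values relate captured signal, and not methylation level, to expression.

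MiGS libraries of one condition were hardly more alike than libraries of different conditions: the mean correlation was 0.546 within and 0.540 between conditions. If unequal rise of signal with abundance were the cause, loess offsets should have set the conditions apart; the difference within minus between was -0.0138. If too few reads were the cause, windows with at least 100 reads should have done so; there it was -0.0836. Both values fall on the side written down in advance as counting against the explanation, but by less than the spread between pairs of libraries (0.452 to 0.741 with loess offsets), a margin added afterwards, so with 2 libraries per condition neither explanation can be excluded. In gene bodies 0 of 16591 were called where 90.9% of simulated 8-fold changes were recovered. This argues against changes of that size in many gene bodies, as far as the common spread of that simulation holds for these libraries. Smaller effects of disease there, and effects of any tested size in windows and gene ends, stay open.

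At peak, 7 of 10 astrocyte markers, 7 of 11 endothelial markers and all 4 measured red blood cell markers were at least 2-fold lower. In the other direction, 1 astrocyte marker was at least 2-fold higher. The largest shift of all genes under another scaling was 0.137. This just missed the bound written down for excluding scaling (0.1 of the astrocyte median of -1.35). None of the scalings tried removed the astrocyte difference: the astrocyte median stayed between -1.49 and -1.28 under each. This second condition was added after the values were seen. A candidate explanation is that fewer cells of every other type passed the F4/80 and CD45 sort at peak. The first test left this open: the lower quartile of 18 neuron and oligodendrocyte markers lay below the upper quartile of 21 astrocyte and endothelial markers (difference -0.311), with medians of -0.21 and -1.18. A second test set the lowest of the 18 (Olig1, -1.41) against the highest of the 4 red blood cell markers (Hbb-bs, -1.59), a difference of 0.171. It was added after its values were seen, so its outcome was known and it cannot count against this explanation. The counting intervals of those 2 genes overlap as well. The 5 oligodendrocyte markers with at least 200 counts went both ways. After scaling Mag was 1.43-fold, Cspg4 1.29-fold and Cnp 1.20-fold higher, and Mobp 1.45-fold and Mbp 1.17-fold lower. Olig1 and Olig2, with fewer counts, were each at least 2-fold lower. Fewer cells of every other type, a loss of some cell types alone and a change within those cells all stay open.

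Monocyte markers were higher at peak. A candidate explanation is monocyte-derived cells in the peak sort; the labels name F4/80 and CD45 but not the levels gated. Of 8 measured markers that monocytes hold in abundance, 6 were at least 2-fold higher and 2 were not: Ccr2 (CPM 16.8 naive and 29.9 peak) and F13a1 (63.7 and 70.3). This fell between the bounds written down for and against the explanation, so the test left it open. Whether the naive levels of Ccr2 and F13a1 would hide a small share of monocytes was not tested. Fn1 reached a CPM of 1011. Monocyte entry and induction of these genes in microglia cannot be told apart in RNA of pooled cells with 1 library per condition. The same limit holds for the lower homeostatic genes and for the higher disease-associated, antigen presentation, interferon, chemokine and cell cycle genes, since monocyte-derived cells in the peak sort could change these too.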
